A study of Drosophila melanogaster x Drosophila sechellia and Drosophila melanogaster
Drosophila sechellia with 2 samples.

How the data were processed

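RNA was surveyed in adult females, whole flies aged 0 to 2 days, of an F1 hybrid between a D. melanogaster strain and a D. sechellia strain, and in a mixed control made from RNA of both strains. Per the labels' protocols, polyadenylated RNA was selected on oligo-dT beads, fragmented, reverse transcribed with random primers and sequenced from both ends, with inserts of about 350 bp ± 20 bp. Each group held 1 library, so no difference below has a replicate check. The design text gives the mixed control the role of measuring false trans signal from errors in the reference genomes, from sequencing and from strand switching.

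For each library the authors deposited cis pairs, with both mates assigned to 1 species, and trans pairs, with mates assigned to different species. Each deposited row gives the chromosome, start and end of 1 mate, and 2 consecutive rows with the same read name form a pair, with 0 pairs of unequal names in any of the files. The deposited score column held the same value in every row and was not used. Build dm3 is named in the submitters' processing notes, and the chromosome names (U, Uextra and Het sequences) belong to that build. The aligner, the rule that assigned a mate to a species and the filters applied are not given in the sources used here. The rows name neither a gene nor, for cis pairs, the species.

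A second deposited set held pairs with both mates on 1 chromosome. Its longest outer distance, from the leftmost start to the rightmost end, was 99944 bp, and the shortest same-chromosome pair outside it spanned 101017 bp; it is called the near set here. The hybrid had 9621305 near cis pairs and 92250 near trans pairs. The mixed control had 9017322 and 81890. Without molecular identifiers, pairs with identical positions cannot be told from PCR copies, and distinct fragments made up 67.9% of near cis pairs in the hybrid and 70.2% in the mixed control. Exact Clopper-Pearson 95% intervals therefore cover counting error only.

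The annotation supplied for this work was of another build. No coordinates were converted, no gene was named and no position was assigned to an exon or intron. The gene lists and single genes fixed in advance and the class of genes with long introns were not analysed by name here, and windows took the place of genes. Whether any of those genes lies at a position given below was not looked up. Results are given by dm3 coordinates (from 1) in windows of 10 kb holding both mates. A second unit was added after the files had been seen. Bins of 200 bp were linked when at least 3 cis pairs of both libraries together joined them, and connected bins formed a linked locus. There were 18367 such loci, with a median span of 1000 bp. A version of this test on all pairs of a locus, not only intron-spanning ones, was also run and is not reported.

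Mates further apart than 500 bp in outer distance were counted as intron-spanning. The term marks distance alone: no intron was read, and pairs just past the limit need not span one. At 2L:11002001-11004200 the median distance of the hybrid's trans pairs so counted was 516 bp. Trans and cis pairs of the 2 libraries were compared with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over the windows or loci tested, at a threshold of 0.05; a window needed at least 20 pairs in each library and 1 trans pair in either. Such a test compares these libraries, not the conditions. It pools the flow cells, in which the libraries have unequal numbers of lanes and the trans shares differ. An exact conditional test stratified by the 3 flow cells, two-sided, with the Mantel-Haenszel ratio of shares, was therefore added after the results had been seen and stands beside the pooled values. Distant pairs were those outside the near set, and a recurrent pair of windows was joined by at least 3 distinct trans fragments; 20 seeded shuffles of the mates gave the number from chance pairing. A test of such pairs between the libraries was added, is not part of the fixed design and is not reported. Cis pairs were scaled to the total of near cis pairs of the library. A fold was called large from 4-fold on, among windows with at least 100 cis pairs in the libraries together, with a floor of 3 counts in place of 0. A first run had applied that floor to counts of 1 and 2 as well; this was changed after its results were seen, and the change altered which windows were the 5 lowest.

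Most mates spanned 37 bp on dm3. Other spans occurred in 3.09% of hybrid and 2.99% of mixed control cis mates. In trans pairs, 0 had such a span in both mates, where 295 and 288 would be had with independent mates, against 44172 and 38621 cis pairs. Mates with another span were therefore counted as D. sechellia reads placed on dm3 across an insertion or deletion. The D. melanogaster share was computed only from cis mates starting where such mates occurred (spans differing by at most 60 bp, at least 3 distinct starts), in 29581 stretches, and it is an estimate that rests on this reading of the files. Windows of 10 kb with at least 100 such mates in each library entered the comparison of shares, with a difference of 30 percentage points called large.

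The read names sorted the lanes into 3 groups, each of which held both libraries: 7 hybrid lanes and 6 mixed control lanes. These groups were taken as flow cells and are called so throughout, and their order is a label only. Of them, 1 held lanes 1, 2 and 3 and another lanes 6, 7 and 8. Lane numbers therefore do not show whether those groups were separate flow cells. On the third flow cell the median distance of near pairs was 278 bp in the hybrid lanes and 274 bp in the mixed control lanes. On the second flow cell 1 mixed control lane had a median of 162 bp and is called the short-insert lane. Flow cells served as the technical batches.

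The window and locus tests were tested on simulated data drawn at the real depths, with 200 changed units. Of 50 windows with an 8-fold higher trans share 64.0% were called, of 50 with a 4-fold higher share 30.0%, and of 50 with a 2-fold higher share 8.0%, among 4491 windows. For 1389 loci the shares were 38.0%, 22.0% and 4.0%. Among the 4291 unchanged windows and 1189 unchanged loci 0 were called. That simulation gave both libraries of a unit the same share in every flow cell. In a further one, with the measured share of each flow cell and no difference between the libraries, the pooled test called 39 windows and 15 loci and the stratified test 0 and 0. Both simulations drew pairs as independent, whereas 63.2% of hybrid and 61.8% of mixed control near trans pairs were distinct fragments. They therefore do not show that the stratified test is free of false calls where copies are many.

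Named positions followed a rule written before the data were examined, in its form for loci without gene names: the 5 with the smallest adjusted p in each direction (with at least 3 distinct trans fragments for those higher in the hybrid), the 5 highest and 5 lowest folds, the 5 largest differences in D. melanogaster share each way, and the 5 distant pairs with most fragments. Linked loci were named after their values were seen. Alternatives fixed at the same time were distinct fragments, other distance limits, windows of 20 kb, other minimum counts, an adjusted p threshold of 0.01, a binomial test against the pooled mixed control share, and leaving out M, U and Het sequences; for folds and shares they were scaling by the median ratio, reweighting and other minimum counts. Single flow cells, tests stratified by flow cell, leaving out the short-insert lane and all settings of linked loci were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.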

Results

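Paired-end sequencing of polyadenylated RNA was used to look for transcripts that join sequence of the D. melanogaster and D. sechellia alleles in F1 hybrid females. A read pair counts as trans when its mates carry different species' sequence, and as cis when both carry that of 1 species. The hybrid library held 9678331 cis and 136916 trans pairs over all chromosomes, and the mixed control, in which RNA of the species was combined after it had been made in separate flies, held 9069982 and 128182. A trans pair in the mixed control cannot stem from joining within a cell. There was 1 library per group and hence no replicate error; all tests compare these libraries by counts of pairs.

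At 2 long loci, intron-spanning trans pairs were frequent in the hybrid and nearly missing from the mixed control. At 3R:17177201-17203200 (26000 bp), 54 of the hybrid's spanning pairs were trans and 251 cis, a trans share of 17.7% (95% interval 13.6 to 22.5%). In the mixed control 2 were trans and 638 cis, a share of 0.313% (0.0379 to 1.12%; Fisher's exact test, two-sided, adjusted p = 3.57e-23). At 2R:6369401-6430800 (61400 bp), the hybrid had 42 trans and 246 cis spanning pairs, or 14.6% (10.7 to 19.2%). The mixed control had 0 trans and 520 cis pairs; 3 counts would be a share of 0.577%, and the exact 95% interval reaches 0.707% (exact test, adjusted p = 5.40e-18). Stratified by flow cell, the exact test gave an adjusted p = 3.35e-17 on 3R and 8.34e-15 on 2R. Trans pairs occurred at each locus in all 7 hybrid lanes. In the third flow cell alone, the shares were 22.7% against 0.641% on 3R and 16.1% against 0 on 2R.

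The trans pairs of these loci met at a shared end, taken as the 200 bp bin with most hybrid trans mates and the bins beside it. Such an end was not particular to these loci. At X:13298601-13307200, all 113 hybrid and all 28 mixed control trans pairs used 1 end, with the hybrid's partners in 1 segment. With partners in 1 segment, pairs share an end whatever joined them. On 3R, 53 of the 54 hybrid trans pairs had a mate starting at 17200846 to 17201006, and their other mates lay in 7 segments between 17178796 and 17198660. On 2R, all 42 had a mate starting at 6419546 to 6419792, with partners in 9 segments between 6371598 and 6406728. Among the other loci called higher in the hybrid when pooled, the most was 3 segments, at X:10674601-10681000. Of the cis spanning pairs of the hybrid, 37.8% on 3R and 48.4% on 2R used the same end. Among pairs that used it, the trans share was 35.8% (28.1 to 44.1%) on 3R and 26.1% (19.5 to 33.6%) on 2R in the hybrid, and 0.539% and 0 of 244 pairs in the mixed control. The median distance of the trans mates was 10416 bp on 3R and 32125 bp on 2R. Pairs of at most 500 bp in these loci were trans in 0.0986% and 0.287% of the hybrid's pairs, and in 0.165% and 0.265% of the mixed control's.

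**Figure D1:**
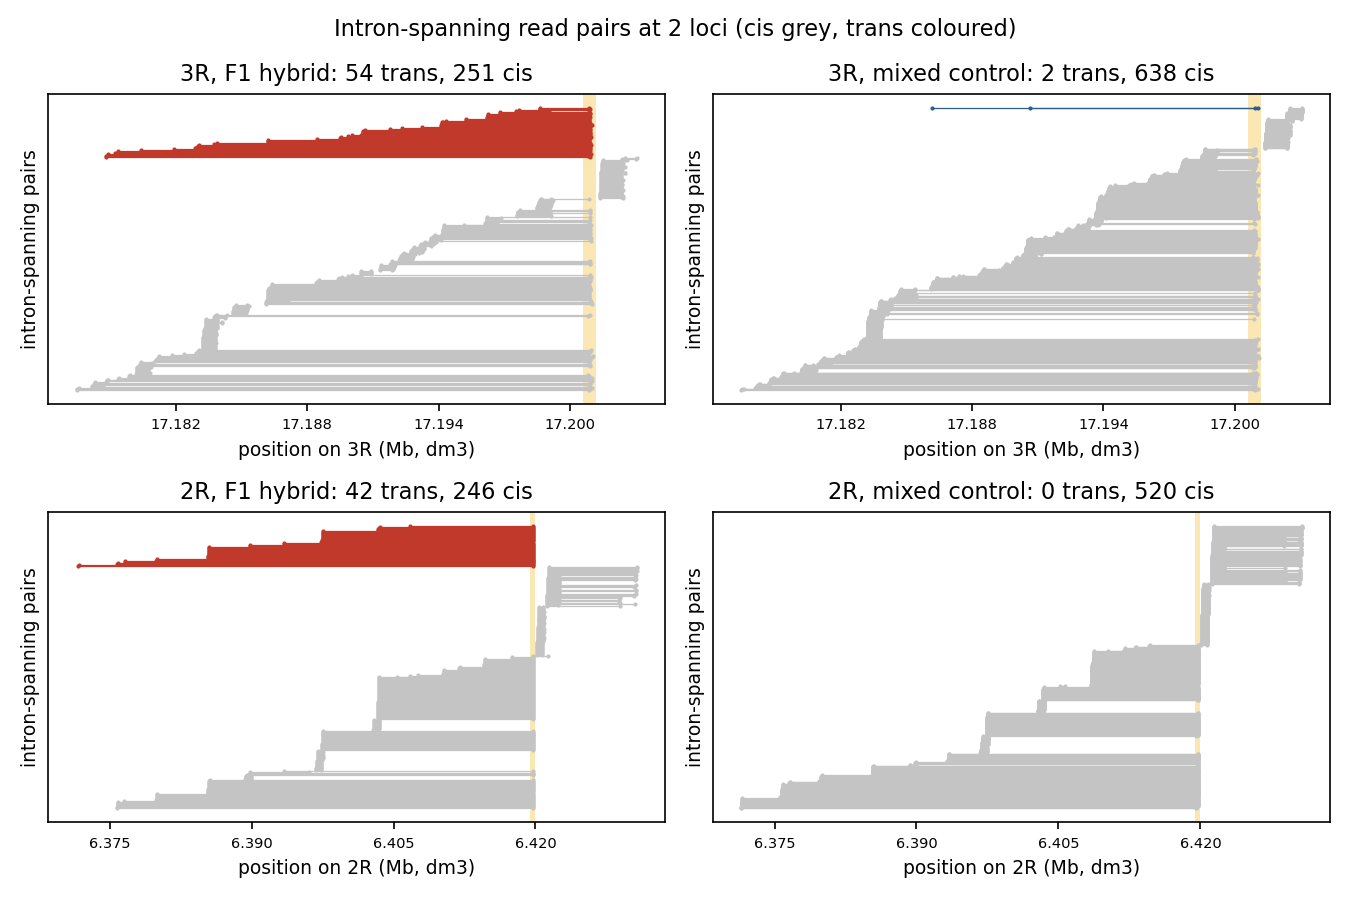
Each horizontal line is 1 intron-spanning read pair, drawn from its left to its right mate against the dm3 position in Mb, with cis pairs in grey, trans pairs in colour and the shared end shaded. The hybrid panels hold 54 trans pairs on 3R and 42 on 2R that end in the shaded part, except 1 on 3R, and the mixed control panels hold 2 and 0.

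Over all 1389 linked loci tested on spanning pairs, pooled over flow cells, 16 had a higher trans share in the hybrid and 9 a lower one, while 71 had an unadjusted p under 0.05. The pooled test does not hold flow cells apart: simulated libraries whose shares differed between flow cells, but not between libraries, gave 15 pooled calls and 0 with the exact test stratified by flow cell. Pairs were independent in that simulation, so it does not cover copies of molecules. Stratified, 8 loci were higher and 2 lower, which kept 7 of the 16 and 2 of the 9. Of the 16 higher loci, 4 had a mixed control share under 1%. Besides the 3R and 2R loci these were 3L:21978201-21980200, with 0.529% against 0.209% (exact test, adjusted p = 8.56e-07), and 3R:5603801-5605600, with 0.681% against 0.0983% (adjusted p = 0.000490). Both passed the stratified exact test (adjusted p = 3.54e-05 and 0.000336), and in the third flow cell alone neither passed (adjusted p = 0.372 and 1). The other 12 carried trans pairs in both libraries, as at X:6424801-6427400, where 32.2% of hybrid and 11.2% of mixed control spanning pairs were trans. There the hybrid lanes of the third flow cell had 41.5% to 52.1% and its mixed control lanes 32.4% and 32.8%. In the first and second flow cells the lanes of both libraries had at most 0.536%. The pooled contrast shrank to a stratified ratio of 1.42 (exact test, adjusted p = 6.58e-09), which rests almost wholly on the third flow cell. X:7793401-7795400 had 19.5% against 13.2%, with a stratified ratio of 1.45 (exact test, adjusted p = 2.65e-18). At X:13298601-13307200 the shares were 15.3% and 5.32%, and at 3L:2782201-2786600 they were 16.3% and 3.88%, but neither passed the exact test in the third flow cell or stratified by flow cell (adjusted p = 1 for both). At 2L:11002001-11004200 the pooled shares were 20.0% and 12.2%, but the third flow cell had the reverse, 28.2% against 35.6% (exact test, adjusted p = 0.0472; stratified 0.181). Loci that were lower in the hybrid included 2R:16831401-16832800, with 30.1% against 40.6%, and 3R:4495201-4499600, with 22.1% against 49.0%. Neither was called on distinct fragments (exact test, adjusted p = 0.652 and 0.0690), and in the third flow cell the first had 29.1% against 29.2%. Both passed the stratified exact test (adjusted p = 1.44e-10 and 0.0189). On distinct fragments 9 of the 16 kept their call, and in the third flow cell alone 5 of the 14 that could be tested did.

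Loci with spanning trans fragments in the hybrid only were more than the mean of random draws but within their range. Those in the mixed control only were fewer than the mean, at the lower end of the range or below it. The 2 counts were not tested together. At least 3 distinct spanning trans fragments in the hybrid and 0 in the mixed control were found at 38 loci, and the reverse at 28. When the trans fragments of each locus were divided at random by its cis fragments, 100 draws gave 29.9 hybrid loci on average (20 to 44, with 38 or more in 9 draws) and 38.8 mixed control loci (28 to 52, with 28 or fewer in 1 draw). Above 1000 bp the hybrid had 24 such loci, a number reached in 2 of 100 draws. With at least 5 fragments the mixed control had 3. The same draws gave 2 to 13 there, with 3 or fewer in 3 of 100. Draws made within flow cells gave 6 to 14, all above the 3 found. The locus at 2R:6369401 led the hybrid list with 40 distinct fragments, and the next, 3R:21732601-21746800, had 7.

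Per library, the near trans share was 0.950% in the hybrid (0.944 to 0.956%) and 0.900% in the mixed control (0.894 to 0.906%), a ratio of 1.06 (Fisher's exact test, p = 2.08e-29). The ratio was 1.04 in the first flow cell, 1.20 in the second and 1.06 in the third, and 1.03 in the second without the short-insert mixed control lane (0.957% against 0.928%, exact test, p = 0.0440). Stratified by flow cell it was 1.07, and 1.05 without that lane (exact test, p = 6.37e-37 and 7.21e-17). These p-values take every pair as independent, although 10 windows held 42.1% of the hybrid's and 44.6% of the mixed control's near trans pairs. Windows with many trans pairs did not run 1 way: the stratified ratio was 0.666 at X:360001-370000 and 1.47 at X:7790001-7800000. Pairs of at most 500 bp had 0.936% and 0.893%, with a stratified ratio of 1.08 (exact test, p = 2.06e-42). Intron-spanning pairs, counted over whole chromosomes, had 1.88% (1.86 to 1.91%) in the hybrid and 1.77% (1.74 to 1.79%) in the mixed control, a ratio of 1.07 (exact test, p = 4.40e-10). These shares include pairs far apart: up to 200000 bp they were 1.08% and 0.964%, and in the near set 1.07% and 0.957%. This pooled direction did not hold within flow cells by the same exact test: the hybrid was lower in the first (1.58% against 1.64%, p = 0.0116), in the second (1.65% against 1.83%, p = 0.000269) and in the third (2.19% against 2.33%, p = 0.000912). The stratified ratio was 0.944 (exact test, p = 2.64e-07), so the pooled excess of the hybrid comes from unequal shares of flow cells: the third, with the highest trans shares, held 48.4% of the hybrid's spanning pairs and 14.3% of the mixed control's. Without the short-insert lane the second flow cell had 1.65% against 1.67% (exact test, p = 0.759). In the near set alone no flow cell showed a difference by the exact test (0.884% against 0.895%, p = 0.554; 0.934% against 0.911%, p = 0.539; 1.26% against 1.32%, p = 0.117), and the stratified ratio was 0.984 (p = 0.272). With a limit of 1000 bp the pooled ratio was 0.920.

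**Figure D2:**
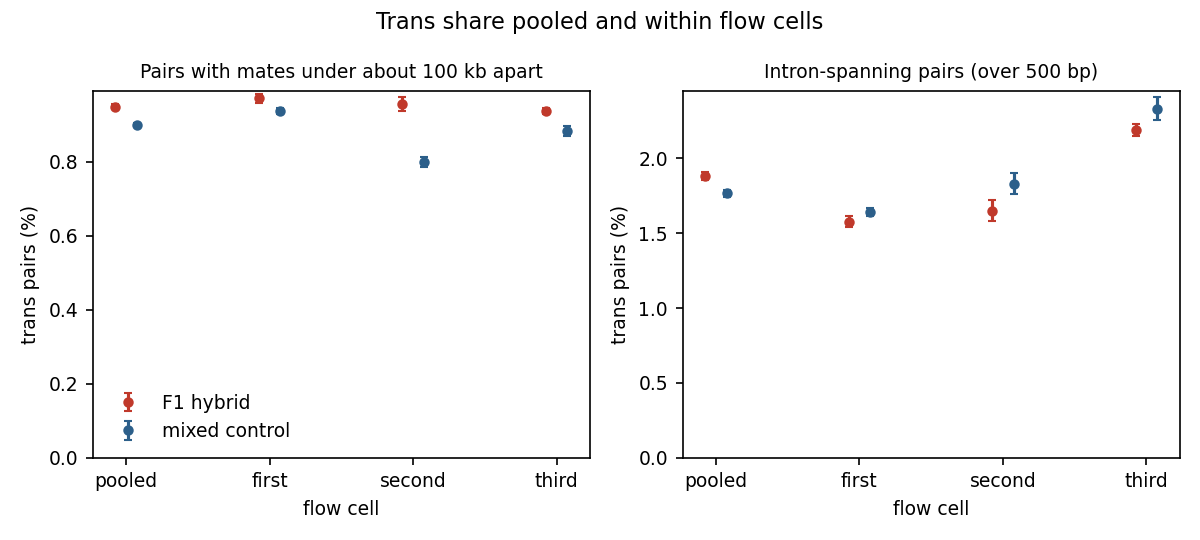
Trans share in percent, pooled and within each flow cell, for near pairs (left) and intron-spanning pairs (right), with exact 95% intervals as bars. Near pairs are higher in the hybrid in every flow cell (0.972%, 0.957% and 0.939% against 0.939%, 0.799% and 0.883%), whereas spanning pairs, far ones included, are higher only when pooled.

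The trans share was higher at long distances of the mates in both libraries. Pooled over lanes, it was at most 1.23% in the hybrid and 1.35% in the mixed control in the classes up to 10000 bp, and from 1000000 bp on it reached 47.9% in the hybrid (47.2 to 48.7%) and 47.5% in the mixed control (46.7 to 48.2%). Between 20000 and 50000 bp, 2.44% of hybrid pairs (153 trans pairs, 2.07 to 2.85%) and 1.28% of mixed control pairs (87 trans pairs, 1.03 to 1.58%) were trans (exact test, adjusted p = 1.84e-06 over 13 classes). In the third flow cell the shares of this class were 2.91% and 1.30% (exact test, adjusted p = 0.00621). Without the 3R and 2R loci, which held 49 of the 153 hybrid trans pairs and 0 of the mixed control's, they were 1.69% and 1.32% (exact test, p = 0.0931; stratified by flow cell 0.304). That class had a stratified ratio of 1.75 with all loci (exact test, adjusted p = 0.000710), and no other class above 400 bp passed. From 500 to 1000 bp the pooled shares were 1.03% and 0.705%, but those in the third flow cell were 1.54% and 1.73%. From 1000 to 2000 bp they were 0.987% and 1.29% pooled, against 0.672% and 0.604% in the third flow cell, and from 2000 to 5000 bp 1.11% and 1.35% pooled, against 0.814% and 0.630%.

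**Figure D3:**
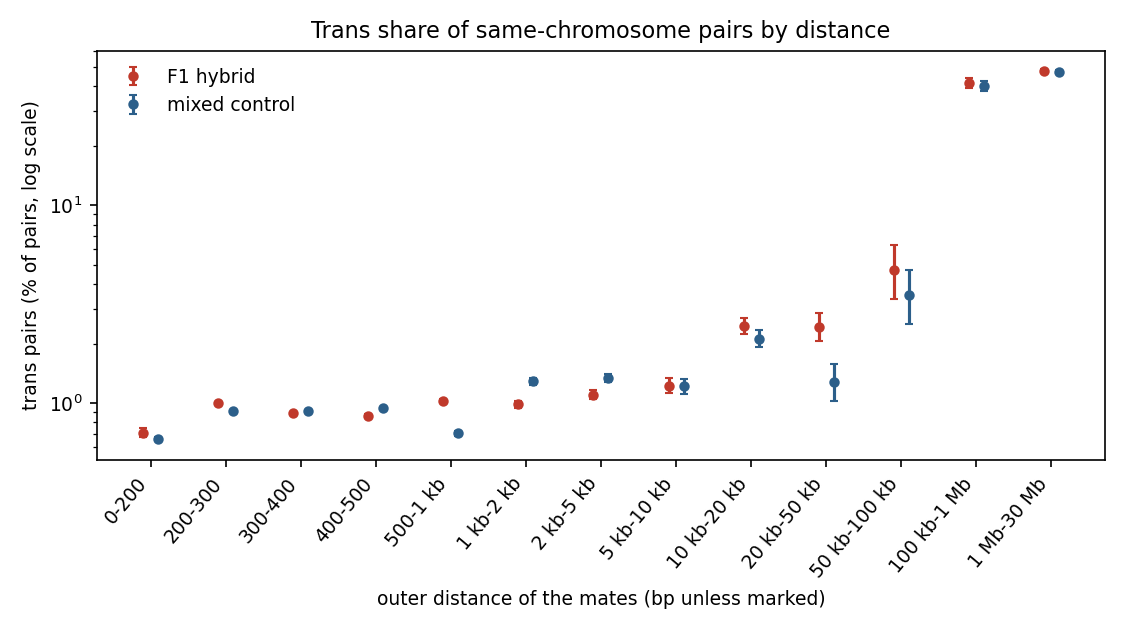
Trans share of same-chromosome pairs (percent, log scale) by the outer distance of the mates, with exact 95% intervals, pooled over lanes. From 20000 to 50000 bp the hybrid lies at 2.44% and the mixed control at 1.28%, and beyond 1000000 bp both lie near 48%.

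Near trans pairs were concentrated in a few 10 kb windows common to both libraries. The 10 windows with most held 42.1% of the hybrid's and 44.6% of the mixed control's, while the median window had 0.228% and 0.220%. The window at 4:1050001-1060000 had most, with 8442 and 6554 trans pairs (8.14% and 7.66%), and 3L:8720001-8730000 had 27.1% and 32.3%. These shares are pooled. Stratified by flow cell, the first turned to a ratio of 0.872 (exact test, adjusted p = 5.60e-12), and the second had 0.967 and was not called. Shares over 5% with at least 20 trans pairs occurred in both libraries in 69 windows.

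Among 4491 windows tested with flow cells pooled, 43 were higher in the hybrid and 33 lower, and 292 had an unadjusted p under 0.05. Simulated libraries that differed between flow cells only, with independent pairs, gave 39 pooled calls and 0 stratified ones. With the exact test stratified by flow cell 22 were higher and 20 lower, which kept 15 of the 43 and 16 of the 33. At 3R:14200001-14210000, 47 of 143 hybrid pairs were trans (32.9%, 25.2 to 41.2%) against 9 of 1398 in the mixed control (0.644%; exact test, adjusted p = 3.18e-40), with 35.3% against 2.16% in the third flow cell. X:7790001-7800000 had 11.7% against 7.74% (exact test, adjusted p = 1.27e-41). Windows X:6420001-6430000 (10.2% against 5.92%), 2L:11000001-11010000 (10.9% against 6.48%) and X:9940001-9950000 (1.93% against 1.59%) were higher when pooled but lower in the third flow cell. Stratified by flow cell, the first 2 were not called (exact test, adjusted p = 1 for both) and the last was lower in the hybrid (ratio 0.843, adjusted p = 3.26e-07). On distinct fragments X:6420001-6430000 was not called (exact test, adjusted p = 1), 2L:11000001-11010000 stayed higher (10.2% against 5.47%, adjusted p = 1.72e-06), and X:9940001-9950000 was lower in the hybrid (adjusted p = 0.00101). Of the windows lower in the hybrid, X:360001-370000 had 9.92% against 19.7% and U:5290001-5300000 had 14 of 27971 pairs (0.0501%) against 405 of 28080 (1.44%; exact test, adjusted p = 2.70e-98). Windows 3L:6040001-6050000 (6.76% against 15.6%), 3L:16310001-16320000 (14.8% against 24.6%) and X:16200001-16210000 (12.5% against 25.5%) were also lower. In the third flow cell the first of these had 0.964% against 1.31% and the last 2.55% against 2.05% (exact test, adjusted p = 1 for both), and their stratified ratios were 0.772 and 0.866, so the pooled contrasts of these 2 come largely from the make-up of flow cells. All 5 windows stayed lower when stratified, with the weakest at X:16200001-16210000 (exact test, adjusted p = 0.00175). Neither 3L window was called on distinct fragments (exact test, adjusted p = 0.524 and 0.270). Of the 76 called windows, 30 were called the same way on distinct fragments, 9 in the third flow cell alone, and 14 turned direction there.

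By chromosome, the trans share of near pairs on 4 was 3.82% in the hybrid and 3.27% in the mixed control, on X 1.52% and 1.32%, and on 3R 0.577% and 0.476%. It was lower in the hybrid on 2R, with 0.697% and 0.778%. Stratified by flow cell, 4 turned to a ratio of 0.944 (exact test, adjusted p = 0.00237), 2R no longer differed (adjusted p = 1), X and 3R had ratios of 1.09 and 1.25, and 3L, with 1.20% and 1.18% pooled, had 1.15 (exact test, adjusted p = 1.64e-36). The strongest contrasts lay outside the main arms. On M, the mitochondrial genome, 32 of 35160 hybrid pairs were trans (0.0910%, 0.0623 to 0.128%) against 190 of 36270 in the mixed control (0.524%, 0.452 to 0.604%; exact test, adjusted p = 3.54e-27 over 15 sequences). On U the shares were 0.0533% and 1.09%. Hybrid lanes ranged from 0.0720% to 0.178% on M and mixed control lanes from 0.410% to 0.681%.

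Pairs joining different chromosomes were counted as a gauge of the pairing of separate molecules. They made up 0.855% of hybrid pairs (0.849 to 0.861%) and 0.874% of mixed control pairs (0.868 to 0.880%; exact test, p = 1.18e-05). Within flow cells the hybrid was not lower by the exact test: the shares were 0.907% and 0.903% in the first (p = 0.559), 1.01% and 0.860% in the second (p = 9.66e-37), and 0.806% and 0.804% in the third (p = 0.844). The second rests on the short-insert mixed control lane, without which it had 1.013% and 1.004% (exact test, p = 0.542). Stratified by flow cell the ratio was 1.03 (exact test, p = 9.86e-09), and 1.004 without that lane (p = 0.445). The pooled deficit of the hybrid comes from the third flow cell, with the lowest share, which held 61.8% of its pairs and 21.7% of the mixed control's. Of these pairs 43.2% were trans in the hybrid and 46.8% in the mixed control, and without M, U and Het sequences 49.1% and 49.1% (exact test, p = 0.857). Within flow cells the trans shares were 46.3% and 48.2%, then 45.1% and 43.6%, where the direction turned, and 41.2% and 45.4%. Without the short-insert lane the second had 45.1% and 47.7%. Free pairing of molecules at the measured species shares gives 49.9% in both libraries.

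Distant trans pairs recurred between the same windows at the rate of chance pairing in the hybrid. At least 3 distinct fragments joined 633 pairs of windows in the hybrid, where shuffled mates gave 633.3 on average, and 502 in the mixed control, where they gave 465.4 with a maximum of 502. Both lists shared 165 pairs. The most frequent hybrid pair, 3L:21970001-21980000 with 3R:11260001-11270000, had 214 distinct trans and 216 cis fragments, and 74 and 75 in the mixed control. The next were 3L:16310001-16320000 with X:9940001-9950000 (77 trans fragments in the hybrid, 71 in the mixed control), 2R:16830001-16840000 with 3R:11260001-11270000 (58 and 17), X:9940001-9950000 with X:13650001-13660000 (52 and 84) and 3R:27040001-27050000 with X:10670001-10680000 (50 and 28). Each was also joined by cis fragments in both libraries.

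Far more windows had a large deficit of cis pairs in the hybrid than a large excess. Whole flies were used, so these counts do not separate the make-up of tissues from expression within cells. Of 5882 windows, 151 had at least 4-fold fewer cis pairs, scaled to the library total, in the hybrid than in the mixed control and 28 at least 4-fold more; 109 and 18 of these passed 4-fold in every flow cell. Folds have no test here, and scaling by the median ratio moved all log2 folds by 0.10. At X:8370001-8380000 the hybrid had 37 cis pairs and the mixed control 10299, a 297-fold lower level (hybrid to mixed ratio 0.00337, counting interval 0.00237 to 0.00464). Ratios were 0.00394 at X:7760001-7770000 (36 and 8567 pairs) and 0.00612 at 2R:18690001-18700000 (39 and 5971 pairs). With 2 hybrid pairs each, 3L:5860001-5870000 had a ratio of 0.00270 (0.000326 to 0.00978) and X:4110001-4120000 one of 0.00495 (0.000597 to 0.0180). The windows lower in the hybrid held 2.53% of the mixed control's cis pairs and 0.259% of the hybrid's.

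In the other direction, X:19700001-19710000 had 497 cis pairs in the hybrid, 427 of them distinct, and 0 in the mixed control, at least 155-fold higher if the 0 is set to a floor of 3 counts, although the counting interval reaches down to 126-fold. The window 3L:12120001-12130000 had 41472 and 3570 pairs, 10.9-fold higher (10.5 to 11.3), with folds of 9.93, 10.8 and 9.78 in the flow cells. Folds were 14.3 at 3L:6110001-6120000 (9.27 to 23.1), 14.2 at 2R:13990001-14000000 (8.27 to 26.4) and 13.6 at 3L:16270001-16280000 (8.52 to 22.9). By chromosome, lower windows made up 3.51% of those on 2L, 3.25% on X, 2.76% on 3L, 1.99% on 3R, 1.63% on 2R and 0 of 93 on 4.

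The species contributed close totals in both libraries. The D. melanogaster share of cis mates at insertions and deletions was 47.6% in the hybrid (457818 of 961808 mates, 47.5 to 47.7%) and 48.3% in the mixed control (420876 of 871736 mates, 48.2 to 48.4%). Across 1426 windows the shares of the hybrid were less spread. Their quartiles were 41.3% and 53.4% in the hybrid and 38.5% and 57.8% in the mixed control, and 70.8% and 51.3% of windows lay between 40% and 60%. Across windows, which are not replicates, the libraries' shares were related with Pearson's r of 0.578 and Spearman's rho of 0.465.

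Windows with a difference of 30 points or more numbered 5 with a higher and 13 with a lower D. melanogaster share in the hybrid. At 2L:10690001-10700000 it was 68.7% in the hybrid (67.5 to 69.9%) and 19.9% in the mixed control (18.5 to 21.4%), and at 2L:2280001-2290000 76.2% and 36.6%. At 3R:15710001-15720000 the shares were 42.8% and 8.84%, at 2R:13400001-13410000 55.8% and 22.3%, and at 3L:12120001-12130000, also among the windows with higher expression, 56.4% and 24.9%. In the other direction X:14090001-14100000 had 29.6% (24.5 to 35.2%) in the hybrid and 74.7% (71.9 to 77.3%) in the mixed control. Shares were 47.4% and 80.9% at 2L:6910001-6920000, 33.2% and 66.7% at X:8790001-8800000, and 29.2% and 62.5% at X:8290001-8300000. At 2R:13550001-13560000 they were 29.4% and 70.3%, but the difference had the opposite sign in the second flow cell (12.5 points). The other 9 named windows kept their direction in every flow cell. The median window had a lower share in the hybrid than in the mixed control on X (46.5% and 50.6%), 3L (48.5% and 50.4%) and 2R (47.2% and 48.1%), and a higher one on 2L (48.5% and 47.2%), 3R (47.7% and 47.0%) and 4 (51.9% and 48.0%, 9 windows).

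**Figure D4:**
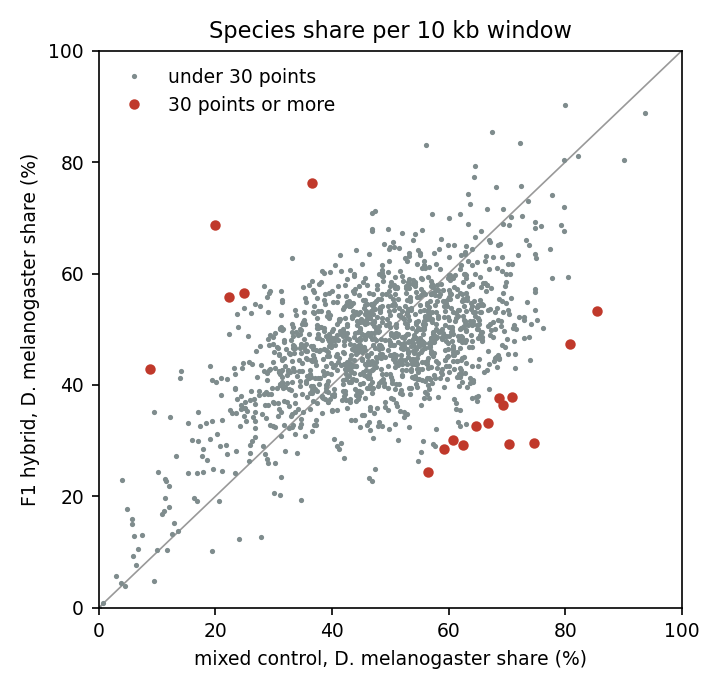
D. melanogaster share (percent of cis mates at insertions and deletions) in the hybrid against the mixed control for 1426 windows of 10 kb with at least 100 such mates in each library; the line marks equal shares. The 18 windows that differ by 30 points or more are drawn larger, and the middle of the cloud is wider along the mixed control axis (quartiles 38.5% and 57.8%) than along the hybrid axis (41.3% and 53.4%).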

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

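Single flow cells, tests stratified by flow cell, leaving out the short-insert lane, the same-chromosome pairs alone, the loci seen in 1 library and all settings of linked loci were chosen after seeing the data; so was the use of distinct fragments for pairs of at most 500 bp. The other settings were fixed in advance. No paired analysis was possible because the groups share only 1 replicate number and hold 1 library each; flow cells, which hold both libraries, served as strata instead. The near trans share stayed higher in the hybrid, with p under the threshold, in all settings tried (ratios from 1.03 to 1.20). None of these settings left out the windows with most trans pairs. The pooled ratio of intron-spanning pairs, 1.07, reversed to 0.920 with a limit of 1000 bp, where the cause was not tested, to 0.962, 0.902 and 0.938 in the first, the second and the third flow cell, 0.991 in the second without the short-insert lane, and 0.944 stratified (0.958 without that lane). The flow cells, unequally shared by the libraries, account for the pooled direction. In the near set alone it was 1.12 pooled, 0.987, 1.02 and 0.960 in the flow cells, 1.01 in the second without the short-insert lane, and 0.984 stratified (0.982 without that lane), the last 6 with exact p over the threshold. The ratio of pairs joining different chromosomes, 0.979, reversed to 1.005, 1.18 and 1.002 in the same order, 1.009 in the second without the short-insert lane, and 1.03 stratified (1.004 without that lane), for the same reason. The ratio of trans shares among them, 0.924, reversed to 1.03 in the second flow cell, but was 0.946 there without the short-insert lane. Totals of windows called, which are not all the same windows, were 43 higher and 33 lower in the pooled test, 22 and 20 stratified (19 and 21 without the short-insert lane), 25 and 10 on distinct fragments, 11 and 6 with intron-spanning pairs only, and 2 and 11 in the third flow cell. At an adjusted p of 0.01, 25 were higher. The one-sided binomial test against the pooled mixed control share gave 422. Totals of loci were 16 higher and 9 lower, 8 and 2 stratified (6 and 2 without the short-insert lane), 9 and 2 on distinct fragments, 5 and 1 in the third flow cell, where the 1 lower is a pooled higher locus that turned, and 8 higher with a limit of 1000 bp. Loci seen in the hybrid only or the mixed control only, 38 and 28, were 7 and 3 with at least 5 fragments, 24 and 14 above 1000 bp, and 3 and 0 with both. For that last 0 in the mixed control, draws within flow cells gave at least 2, and draws that ignored flow cells gave 0 in 8 of 100. Recurrent distant pairs of windows, 633 and 502, were 169 and 133 with at least 5 fragments, where shuffled mates gave up to 172 and up to 127, so the mixed control exceeded every shuffle. Windows with 4-fold higher expression, 28, were 56 with at least 20 pairs. Windows with a D. melanogaster share 30 points higher or lower, 5 and 13 of 1426, were 42 and 116 of 3354 with at least 20 mates. In the third flow cell, where 329 windows had enough mates, they were 5 and 3. The D. melanogaster share of 47.6% in the hybrid was 47.1% on distinct fragments, and the 48.3% of the mixed control was 48.5% on distinct fragments and 48.5% as the median over windows. Fewer units could be tested under some settings. The third flow cell alone had 3275 windows against 4491 and 516 loci against 1389, intron-spanning pairs 1167 windows, and the limit of 1000 bp 727 loci. Lower totals there are thus not all calls that failed. For changed counts with no reason given, the cause was not tested. Of 119 values under other settings 62 stayed on the same side of the threshold, within 1.5 times the count or within the interval. The alternatives for gene lists and for long introns were not run, because no gene was named. At these depths a 2-fold higher trans share was called in 4.0% of simulated loci, so that loci not called are not shown to lack trans pairs.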

Other observations

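The tests of duplicates, of flow cells, of the mixed control share and of loci picked on part of the flow cells, and the comparisons of mitochondrial pair numbers, were chosen only after the result was seen; the tests of short pairs at the shared end, of the range of ratios over windows and of the spread of species shares were written before theirs was, although each pattern had been seen. The range of ratios over windows had first been taken without U, and U was included after that result had been seen. A first test of joining between alleles was run on loci chosen for the pattern, which made it void, and was replaced by loci picked on part of the flow cells; that repeat was first read in favour of such joining, which 1 hybrid library does not allow. Tests of lane composition and of the class from 20000 to 50000 bp as patterns of their own were also run and left out.

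Other features of the expression data lie outside the comparisons. In 9 windows the D. melanogaster share was under 10% in both libraries, and in 0 windows it was over 90% in both. The 3R:14200001-14210000 window, with 47 trans pairs of 143 in the hybrid, had 96 cis pairs there against 1389 in the mixed control, and 43 of its trans pairs were distinct fragments.

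At the 3R and 2R loci, trans pairs that share an end made up a large part of spanning pairs in the hybrid. A shared end also occurred at loci with trans pairs in the mixed control, so by itself it does not point to a cause. Where the partners form 1 segment, as at X:13298601-13307200, an end is shared whatever the cause. At the 3R and 2R loci 1 end met partners in 7 and 9 segments, and a comparison with single segments does not bear on this feature. Copies of a few molecules are argued against by 96.9% distinct fragments among these trans pairs, and fragment length or lanes by the third flow cell alone (19.6% against 0.402%, Fisher's exact test, two-sided, p = 4.18e-16). Joining of separate molecules during library preparation would occur in the mixed control too, where 0.172% of the spanning pairs of these loci were trans (0.0209 to 0.621%, against 13.3 to 19.4% in the hybrid). The loci were named for that contrast, so these shares restate it. Both were also picked on the first and second flow cells alone. The third then had 22.7% against 0.641% on 3R and 16.1% against 0 on 2R. Errors of species assignment at the shared end would reach short pairs there, and of 234 hybrid pairs of at most 500 bp with a mate at that end 0 were trans, where 3 counts would be 1.28% and the exact interval reaches 1.56%, although an error that moved both mates alike would not show. The test does not cover the partner mates and can miss false trans pairs. At 3L:2782201-2786600, 8.20% of the mixed control's spanning pairs at the shared end were trans, yet its short pairs there were 1 trans and 140 cis. A candidate explanation is joining of RNA from the homologous alleles at a common exon, a hypothesis left open: of 4 loci picked on the first and second flow cells 3 (75%) were higher in the third at an exact p under 0.05 without adjustment, 1 of them only weakly (3L:21978201-21980200, 0.573% against 0.200%, adjusted p = 0.372 over all loci), but any cause particular to the 1 hybrid library would repeat there too.

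On M, the hybrid's trans share was lower than in the mixed control. A general difference in the rate of joined pairs is argued against by the ratio of 0.174 on M, since 85 windows with at least 10000 pairs in each library had ratios of 0.444 to 2.03 in their central 90%, although 1, on U, had a lower one (0.0347). Fewer mitochondrial pairs are argued against by the third flow cell, where M held 93.0% as large a part of near cis pairs in the hybrid and the trans shares were 0.0814% (0.0527 to 0.120%) and 0.623% (0.484 to 0.790%); the pooled number of cis pairs, 97.4% of the mixed control's, rests on the short-insert lane and was 184% without it, and by part of near cis pairs the hybrid had 20.0% in the second flow cell (69.1% without that lane). A hybrid that carries the mitochondrial genome of 1 parent would have few molecules of the other species to join, which may account for the pattern; all mates of near pairs on M spanned 37 bp, so the species of its cis pairs could not be read and this stays untested. The window on U with a lower ratio, U:5290001-5300000, had 0.0501% against 1.44%, with no test of its source.

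The D. melanogaster share varied less across windows in the hybrid, where alleles share a cell, than in the mixed control. Depth does not account for this: with every window thinned to 100 mates in each library, the interquartile range was narrower in the hybrid in 100 of 100 thinnings (13.1 against 20.1 points on average). On distinct fragments the hybrid's range was 58.4% of the mixed control's, and in the third flow cell 58.0%, which argues against duplicates and lanes. Differences between species that act through shared factors may be evened out in a common cell, while differences between the flies pooled for the control could widen its range in the same way, and 1 library of each kind cannot separate these.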
